A study of Homo sapiens with 17 samples.

How the data were processed

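RNA from TIG-1 human lung fibroblasts and from clones carrying a TERT vector, a vector for the SV40 early antigens (SV40EA) or both was measured on 17 arrays of 3 platforms. CodeLink held 7 arrays, Agilent 4 and Affymetrix 6, and all cells were collected while growing exponentially, per the labels' protocols. The number in each sample title, such as 65 in TERT6-65, was not explained in the labels and is called the title number here. Groups were taken from the titles, although some CodeLink scanner headers name the ST11 clone differently and the treatment protocols of the CodeLink TERT6 arrays do not mention the TERT transfection. On CodeLink they were the parent TIG-1 (n = 1), TERT6 (n = 2), SV12 with SV40EA (n = 2) and ST11 with both vectors (n = 2). On Agilent they were the parent (n = 1), TERT6 (n = 2) and ST11 (n = 1). On Affymetrix they were the parent (n = 1), the clones TERT5 and TERT8 that the labels call mortal with an elongated lifespan (n = 2), and TERT6 (n = 3). Arrays of 1 clone at different title numbers were treated as the replicates of that clone. No label said that they were separate cultures, so p-values measured the spread between these arrays, which may be technical in part. A vector and the clone that carried it could not be told apart.

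The deposited CodeLink scanner files held a quality flag for each spot, and the deposited Agilent files held flags for spots well above background and for outliers. The deposited CodeLink files gave the mean intensity of each spot and the median intensity of its local background on a linear scale, not normalized, per the file headers. The deposited Agilent files came from Agilent Feature Extraction 9.1, per the file headers and the submitters' processing notes. Their processed signal was a background-subtracted intensity on a linear scale, not normalized between arrays. The deposited Affymetrix table held the GCOS signal, an intensity scaled by the authors so that the mean without the lowest and highest 2% of probe sets was 500 on every array, as found from the values; the version of GCOS is not given in the sources used here. The CodeLink values of the authors were found to be the background-subtracted intensity divided by a constant for each array. Their Agilent values were the processed signal rounded, within a relative tolerance of 0.005. The column medians of the authors' tables lay between 0.974 and 0.981 for CodeLink, between 170.0 and 181.0 for Agilent and between 61.3 and 74.3 for Affymetrix.

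Values were computed in R 4.3.3 with version 3.58.1 of limma and version 1.17.8 of data.table, and files were read in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. CodeLink intensities were background-corrected by normexp with an offset of 50, converted to log2 and quantile-normalized. Agilent values were log2 of the processed signal minus the 75th percentile of the array. Affymetrix values were log2 of the signal plus 16, with the authors' scaling kept. CodeLink probes had to be unflagged on at least 2 arrays. The design had assumed a letter for a good flag, whereas the files code an unflagged spot as 0, an empty spot as 2 and other faults as 3. Spots with other faults and Agilent outlier spots were set to missing, repeated spots of a probe were averaged and probes with a missing value were dropped. Agilent probes had to be well above background on at least 1 array, and Affymetrix probe sets had to have a mean at or above the median probe set. The probe with the highest mean stood for each gene. After the filters 13080, 14607 and 12189 genes remained on CodeLink, Agilent and Affymetrix.

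The CodeLink values of the authors carry other identifiers than the scanner files. They were linked to spots by value, which matched for 20223 of 20470 probes within a tolerance of 1e-05, and 99.2% of the RefSeq identifiers that could be checked named the same gene. Genes were named through the platform annotation with symbols brought up to date through the RefSeq gene table of assembly GRCh38.p14. Of 20470 CodeLink probes, 16174 had 1 gene symbol, 87 several and 4209 none. The counts were 31332, 93 and 13590 of 45015 for Agilent and 41097, 1801 and 11777 of 54675 for Affymetrix. Probes with several symbols were not used. Genes that would tell the sex of a donor were left out.

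On CodeLink, 94.2% to 96.9% of 20532 spots were unflagged, and the median local background was 64.0 to 74.0 against a median background-subtracted signal of 238.8 to 309.1. On Agilent, 59.5% to 66.5% of 43376 spots were well above background. The Affymetrix table carried no detection calls in the columns used here, so values near the bottom of its scale had no stated limit. The number of arrays, above all the 1 parent array on each platform, limits the precision. Where no probe of a gene was above background on every array of a side, the fold is given as a lower bound: the mean of the brighter side against the higher, on each array of the dimmer side, of the lowest signal above background and the probe's own signal.

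The comparisons, filters, gene lists, rules for naming genes and alternatives were chosen before the data were examined. All gene tests were limma fits (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The SV40EA effect and the TERT effect came from an additive model of both vectors over the 7 CodeLink arrays. The ST11 against SV12 difference and the TERT by SV40EA interaction came from a model with 4 groups. The interaction was the ST11 minus SV12 difference minus the TERT6 minus parent difference. On Affymetrix, TERT6 was compared with all mortal cells in a 2-group model, and with the mortal TERT clones, and these with the parent, in a 3-group model. The lone parent array was assumed to vary like the other groups. TERT6-65 minus parent on 3 platforms, and TERT6-217 minus TERT6-65 on 2, were tested against 0 with 1 difference for each platform. These differences repeat the measurement of samples with the same title, so their p-values measure how well the platforms accord, not the spread between cultures. Genes were compared on Agilent alone without a test.

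The 20 gene lists held p53 target genes, DNA replication and E2F target genes, mitosis genes, DNA repair genes, extracellular matrix genes, contractile and myofibroblast genes, senescence-associated secreted factors, interferon-stimulated genes, telomerase and shelterin genes, senescence regulators, HOX and lung mesenchyme transcription factor genes, imprinted genes, glycolysis and hypoxia genes, cholesterol synthesis genes, cancer-testis antigen genes, and markers of fibroblasts and of epithelial, endothelial, blood and neural cells. They were tested with camera at a preset correlation of 0.01 and, beside it, an estimated correlation, with adjustment over the lists of a comparison. With an estimated correlation camera also takes the residual degrees of freedom of the arrays, 1 to 4 here. A call lost in that form therefore need not reflect correlation between genes. Lists with fewer than 5 measured members were described without a test. On Agilent, the median of a list was given with its percentile among 10000 random lists of the same size matched on mean expression. For some lists a median is given over members well above background on at least 1 of the arrays compared, with each undetected level raised to the floor, the lowest signal well above background on its array. The text names TERT, CDKN1A, CDKN2A and RB1 throughout, fitted without the filter where they missed it, the 5 called genes with the highest and the 5 with the lowest log2 change in each comparison, and up to 4 called genes of each list with the largest absolute change. Where a comparison had no call, the 5 highest and 5 lowest log2 changes at an unadjusted p under 0.01 are named, and on Agilent alone the 5 highest and 5 lowest among genes well above background on both sides. A further gene of this rule is not analysed here.

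Alternatives covered the authors' value tables, other background corrections and normalizations, other pseudocounts and filters, the mean of all probes of a gene, an intensity trend in the prior, the title number as a covariate, a 4-group model in place of the additive model, equal scaling of the platforms, leaving out each array or platform, and the estimated correlation. The fits were tested on simulated data with 200 changed genes. At a 2-fold change, 92% were recovered for the SV40EA effect, 90% for the TERT effect, 93% for ST11 against SV12, 53% for the interaction, 7% for TERT6 against mortal cells, 81% for TERT6-65 against the parent and 8% for TERT6-217 against TERT6-65. At a 4-fold change these shares were 100%, 99%, 100%, 98%, 60%, 97% and 89%. Unchanged genes called in the same simulations numbered 6, 14, 12, 9, 4, 15 and 16, in the same order. In TERT6 against mortal cells 1 of 17 lists was called without a shift. The 3-group Affymetrix comparisons recovered 0% at either size.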

Results

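Gene expression was measured in TIG-1 human lung fibroblasts, a cell strain with a limited lifespan, and in clones isolated from them after transfer of vectors for TERT, the catalytic subunit of telomerase, for the SV40 early antigens (SV40EA, viral proteins that transform cells) or for both. CodeLink arrays covered TIG-1-45 (n = 1) and the clones TERT6 (n = 2), SV12 with SV40EA (n = 2) and ST11 with both vectors (n = 2). Agilent arrays covered TIG-1-45 (n = 1), TERT6-65, TERT6-217 and ST11-196, with 1 array for each title. Affymetrix arrays covered TIG-1-45 (n = 1), TERT5-71 and TERT8-70, labelled mortal with an elongated lifespan (n = 2), and TERT6-65, TERT6-121 and TERT6-217 (n = 3). The labels call the parent and SV12 mortal, TERT6-65 and TERT6-85 immortal-competent on CodeLink, TERT6-121 and TERT6-217 immortal, ST11-65 immortal-competent and ST11-106 and ST11-196 immortal. The Agilent array of TERT6-65 was labelled mortal, unlike its namesakes on the other platforms. Median signals lay between 238.8 and 309.1 on CodeLink, between 186.1 and 200.8 on Agilent and between 61.3 and 74.3 on Affymetrix, in the units of each platform. Each platform held 1 array of the parent, and the small number of arrays limits the precision of every value below.

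TERT transcripts lay above the parent in every clone labelled as carrying the TERT vector, and CDKN2A, which encodes the cell cycle inhibitor p16, moved apart between arrays of the TERT6 clone. On CodeLink, TERT exceeded the parent by 5.04 and 4.80 on the log2 scale in TERT6 and by 5.64 and 5.63 in ST11, against 0.19 and 0.06 in SV12. On Affymetrix the TERT difference from the parent was 7.65 in TERT5, 6.34 in TERT8, 6.90 in TERT6-65, 5.08 in TERT6-121 and 2.22 in TERT6-217. CDKN2A lay above the parent by 0.86 and 0.85 in TERT6, 2.27 and 2.30 in SV12 and 2.96 and 2.59 in ST11 on CodeLink. Within TERT6, the CDKN2A difference from the parent was 1.67 at TERT6-65 and −3.03 at TERT6-217 on Agilent. On Affymetrix it was 0.84 at TERT6-65, −1.82 at TERT6-121 and −5.14 at TERT6-217, beside −0.61 in TERT5 and 0.48 in TERT8. These are single arrays without a test. The Affymetrix values of CDKN2A are those of its probe set with the highest mean. In TERT6 against mortal cells 1 of its 2 further probe sets had the same sign.

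**Figure D1:**
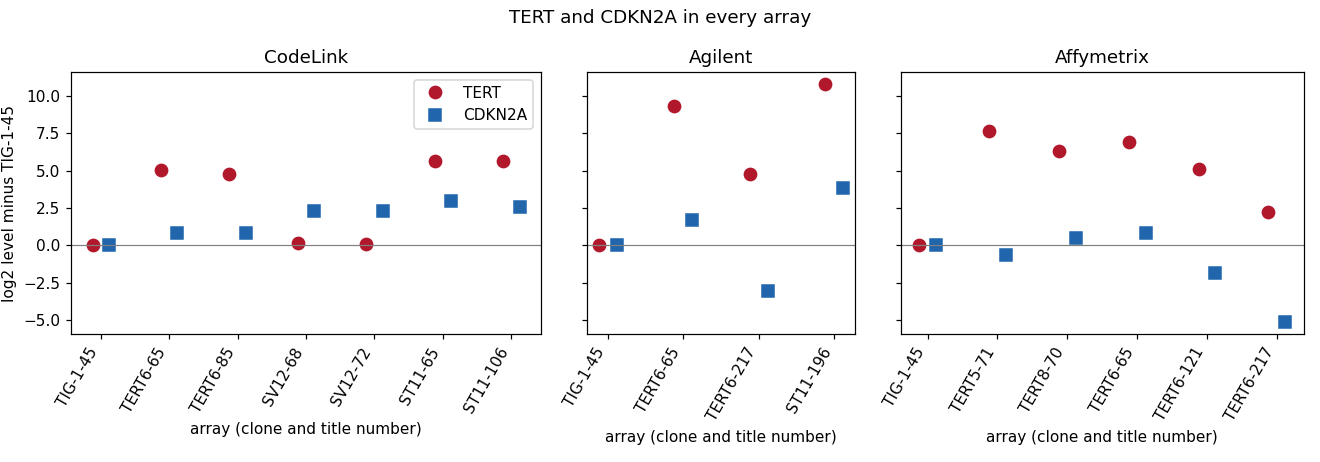
Log2 level of TERT and of CDKN2A minus that of TIG-1-45 on the same platform (vertical axis) for each array on CodeLink, Agilent and Affymetrix, with the parent at 0 (circles TERT, squares CDKN2A). TERT lay above the parent in all clones with the TERT vector, and CDKN2A lay at −3.03 on Agilent and −5.14 on Affymetrix in TERT6-217.

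The SV40EA comparison asked which genes differed between the 4 CodeLink arrays with the viral antigens and the 3 without, at equal TERT status. IL1B, a cytokine of inflammation, rose by 5.91 on the log2 scale (14.71 ± 0.60, SD, n = 4, against 8.73 ± 0.11, n = 3), CXCL8, which attracts neutrophils, by 4.10, and CXCL2 by 3.30. The complement gene C3 was at least 14.8-fold higher, and ESM1 and G0S2 rose by 3.89 and 3.81. Genes of the extracellular matrix were among those that were lower. The log2 change was −2.61 for COL1A1 and −3.39 for COL1A2, the chains of type I collagen, −3.07 for COL6A3, −3.30 for TGFBI and −6.01 for SPON2, a secreted matrix protein. WFDC1 was at least 25-fold lower and BMP4, a signalling protein of lung development, at least 18.0-fold lower. These bounds, like that of C3, compare the means of both sides without holding TERT status equal. For WFDC1 the fit at equal TERT status gave −4.51, or 22.8-fold. Its log2 difference was −2.26 in SV12 minus parent and −6.01 in ST11 minus TERT6, with no array above background in SV12 or ST11. IGFBP5 changed by −4.50, and the globin gene HBD by −4.46, with a spread of 3.20 (SD, n = 3) in the arrays without SV40EA. HBD differed by −1.24 in SV12 minus parent and by −6.61 in ST11 minus TERT6, and SPON2 by −3.47 and −7.71. Much of both changes thus came from high levels in TERT6.

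By list, 20 of 30 DNA replication and E2F target genes rose with SV40EA and 0 fell (29 rose adjusted over the list alone), with a median log2 change of 1.39. Among them FEN1, which trims Okazaki fragments, rose by 2.62, RFC4 by 2.61, MCM7 by 2.01 and CHAF1A by 1.97. Of 27 mitosis genes 13 rose and 0 fell (22 adjusted over the list alone), with a median of 1.33, led by AURKB (2.55), MAD2L1 (2.28), NUF2 (2.11) and CDK1 (2.09). Of 14 DNA repair genes 10 rose (11 adjusted over the list alone), with a median of 0.87, among them the helicase gene BLM (2.46), RAD51AP1 (1.86), H2AX (1.51) and BARD1 (1.12). Extracellular matrix genes went the other way. Of 29, 20 fell and 0 rose (21 fell and 2 rose adjusted over the list alone), with a median of −1.58, including FBLN5 at −3.54. Of 10 fibroblast markers 8 fell (9 adjusted over the list alone), with a median of −1.21, including LUM (−2.37) and FAP (−1.54). The camera test gave adjusted p = 3.35e-13 for replication, 8.26e-09 for mitosis, 7.39e-06 for repair, 3.23e-12 for matrix and 3.45e-07 for fibroblast markers. With an estimated correlation these became adjusted p = 0.445, 0.527, 0.445, 0.294 and 0.0976.

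The cell cycle lists differed between the pairs behind this comparison. The replication list had a median of 0.57 in SV12 minus parent and 1.88 in ST11 minus TERT6, and the mitosis list 0.24 and 2.04. The matrix list was negative in both, at −0.98 and −1.64. In TERT6 minus parent, the replication and mitosis medians were −0.66 and −1.62, so TERT6 lay below the parent in these genes. The plot of list medians by array shows the same values for single arrays.

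**Figure D2:**
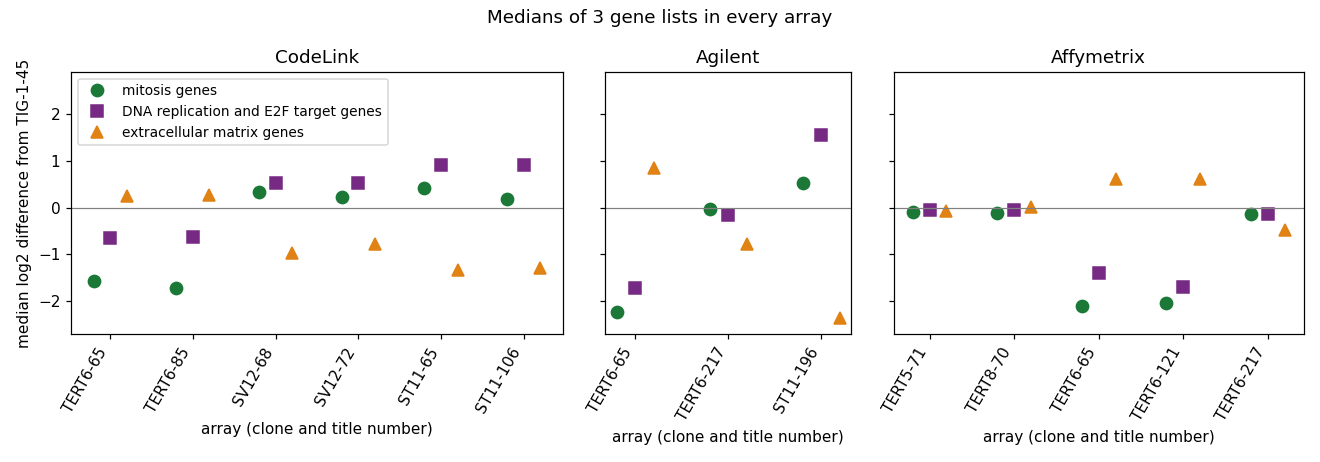
Median log2 level minus TIG-1-45 (vertical axis) of the mitosis, replication and extracellular matrix lists (circles, squares and triangles) for each array of a clone on 3 platforms. The mitosis list lay at −1.57 and −1.72 in TERT6 on CodeLink and at −2.09 in TERT6-65, −2.05 in TERT6-121 and −0.13 in TERT6-217 on Affymetrix.

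Other lists moved less with SV40EA. Of 14 telomerase and shelterin genes 5 rose (9 rose and 1 fell adjusted over the list alone), with a median of 0.39 and adjusted p = 0.00108, against adjusted p = 0.527 with an estimated correlation. They included NHP2 (0.79), ACD (0.72), DKC1 (0.63) and GAR1 (0.51), parts of the telomerase or shelterin complexes. Of 12 contractile genes 1 fell, MYLK at −2.49, with a list median of −0.22 (adjusted p = 0.0438, and adjusted p = 0.69 with an estimated correlation). Among 24 p53 target genes 4 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of −0.26 (adjusted p = 0.0512), and the list passed the test in 8 of 17 alternatives. Those that fell were TP53INP1 (−1.19), PHLDA3 (−0.85), RRM2B (−0.76) and ZMAT3 (−0.73), and CDKN1A, which encodes the cell cycle inhibitor p21, had −1.15 (adjusted p = 0.0612). Senescence-associated secreted factors were mixed, with 5 of 28 up and 4 down (11 and 4 adjusted over the list alone), a median of 0.45 and adjusted p = 0.0948.

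Among senescence regulators 3 of 18 rose, CDKN2A by 2.07 (adjusted p = 0.000985), ETS1 by 0.96 and RBL1 by 0.37, while RB1 had 0.03 (adjusted p = 0.867), and the list gave adjusted p = 0.605. TERT had 0.48 (adjusted p = 0.0732). Of 22 interferon-stimulated genes 3 rose, HERC5 by 1.51, OASL by 0.95 and PSMB8 by 0.65, with a list median of −0.11 (adjusted p = 0.87). Of 15 HOX and lung mesenchyme genes 2 fell, FOXF1 (−1.99) and TBX2 (−0.57), both transcription factors of the lung mesenchyme, with adjusted p = 0.322 for the list. Of 16 imprinted genes 1 fell, SNRPN at −1.22 (list adjusted p = 0.122). Glycolysis and hypoxia genes had 2 of 20 up, ENO2 (0.60) and PGAM1 (0.48), and 2 down, P4HA1 (−0.83) and ADM (−0.76), with adjusted p = 0.605. Of 15 cholesterol synthesis genes 2 rose, ACAT2 (1.05) and EBP (0.70), with adjusted p = 0.41. None of 13 cancer-testis antigen genes passed the test in limma, where 3965 of all genes had an unadjusted p under 0.05, and the list's adjusted p was 0.605.

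Among markers of other cell types, EPCAM (1.06) and SFTPC (0.78) rose of 13 epithelial markers (adjusted p = 0.605), and TEK fell (−2.20) among 8 endothelial markers (adjusted p = 0.71). Of 8 neural markers NES (−2.18), TUBB3 (−1.03) and SYP (−0.60) fell (adjusted p = 0.0948), and of 7 blood cell markers limma called 0 (adjusted p = 0.41).

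In limma's additive model 1011 genes rose and 1019 fell with SV40EA among 13080 tested, 302 and 318 of them by over 2-fold. Without the parent array the SV40EA effect is ST11 minus TERT6 by construction, so that count is of another contrast. The count was 4007 without the parent array, 752 and 690 without TERT6 replicate 1 or 2, 1148 and 863 without ST11 replicate 1 or 2, 768 with the title number as a covariate and 3394 with a 4-group model. A second probe of COL1A1 had the opposite sign, as had 1 of 3 further probes of COL1A2, and with the mean of all probes COL1A1 had −1.25, COL1A2 −0.77, IGFBP5 −2.86, SNRPN −0.52 and AURKB 1.29.

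On Agilent, the array of ST11-196 was set against the mean of the TERT6 arrays, a contrast from other arrays of the same clones. The title TERT6-65 stands on both platforms and enters both contrasts with the same sign. Part of the shared direction below is therefore built in. Of 1940 genes called for SV40EA on CodeLink and measured on Agilent, 1736 (89.5%) had the same sign there, against 67.3% of all 11103 shared genes. Pearson's r across the called genes was 0.743, and across all shared genes 0.479; genes are not independent replicates. CDKN2A had a difference of 4.51 in this Agilent contrast, in which the arrays averaged lay apart, at 1.67 above the parent in TERT6-65 and −3.03 in TERT6-217.

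**Figure D3:**
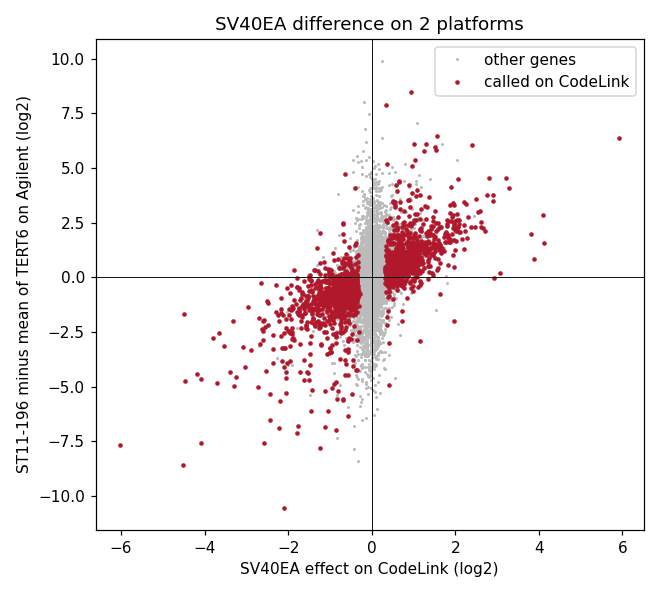
Log2 change with SV40EA on CodeLink (horizontal axis) and log2 difference of ST11-196 minus the mean of TERT6 on Agilent (vertical axis), 1 point for each gene measured on both, red where called on CodeLink and grey elsewhere. Of 1940 called genes, 1736 had the same sign on both axes.

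The TERT comparison asked what differed between the 4 CodeLink arrays with the TERT vector and the 3 without, at equal SV40EA status. TERT itself rose by 5.28 (adjusted p = 6.74e-05; 12.59 ± 0.42, SD, n = 4, against 7.39 ± 0.09, n = 3). Beside it KRT8, a keratin of simple epithelia, rose by 1.06 (adjusted p = 0.0171) and IGDCC4 by 1.06 (adjusted p = 0.0479). The fallen genes were TP53I11 at −2.39 (adjusted p = 0.00203), GAL, which encodes the neuropeptide galanin, at −1.89 (adjusted p = 0.0232) and the potassium channel gene KCNK2 at −1.12 (adjusted p = 0.0232). CDKN2A had 0.64 (adjusted p = 0.239), CDKN1A 0.58 (adjusted p = 0.708) and RB1 0.05 (adjusted p = 0.973). None of 27 mitosis genes passed the limma test, which gave 1197 genes over all at an unadjusted p under 0.05, but all 27 were negative, with a median of −0.53. The list's adjusted p was 1.94e-06, and adjusted p = 0.981 with an estimated correlation. For p53 target genes the median was 0.08, with 19 of 24 positive (adjusted p = 0.0404, and adjusted p = 0.981 with an estimated correlation).

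Of 13080 genes, limma called 3 up and 3 down for TERT. The count was 468 without the parent array, 2 without TERT6 replicate 1 or 2, SV12 replicate 1 or ST11 replicate 1 or 2, 1 with the title number as a covariate and 270 with a 4-group model. Without the parent array, where the TERT effect is ST11 minus SV12 by construction, the mitosis list's median became 0.17, of the opposite sign.

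Within SV40EA-transformed cells, ST11 (labelled immortal or immortal-competent) was compared with SV12 (labelled mortal), n = 2 each. TERT rose by 5.51 (adjusted p = 4.33e-05), IFITM1, an interferon-induced membrane protein that restricts virus entry, by 3.26, SERPINF1 by 2.92, RTEL1, a helicase that acts at telomeres and replication forks, by 2.81, VAMP8 by 2.61 and the matrix proteoglycan gene LUM by 2.35. The membrane skeleton gene EPB41L3 fell (−3.54), as did the chemokine gene CXCL6 (−2.78), TP53I11 (−2.32) and THBS1 (−2.30), which encodes thrombospondin. The smooth muscle genes ACTG2 (−2.49), TAGLN (−1.75), TPM1 (−1.14) and CALD1 (−0.70) fell, 4 of 12 contractile genes (7 adjusted over the list alone; median −0.29; list adjusted p = 0.000924, and adjusted p = 0.39 with an estimated correlation). Of 30 replication genes 6 rose (19 adjusted over the list alone), among them TYMS (1.10), PCNA (1.02), POLA1 (0.86) and LIG1 (0.55). The list's median was 0.42 (adjusted p = 1.04e-08, and adjusted p = 0.117 with an estimated correlation). Of 14 repair genes 2 rose, RAD51AP1 (0.89) and H2AX (0.54), with a median of 0.36 (adjusted p = 0.00337, and adjusted p = 0.338 with an estimated correlation).

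In other lists of ST11 against SV12, of 29 matrix genes 4 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of −0.16, COL6A3 at −1.22 and FBLN5 at −1.30 (adjusted p = 0.0175, and adjusted p = 0.338 with an estimated correlation). The p53 targets had 0 of 24 called in limma, where 3027 of all genes had an unadjusted p under 0.05, and 4 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.00614, and adjusted p = 0.451 with an estimated correlation). The mitosis list had 0 of 27 called, 5 adjusted over the list alone, and a median of 0.17 (adjusted p = 0.0473, and adjusted p = 0.576 with an estimated correlation). Secreted factors had a median of −0.30 and the neural markers −0.17, with IL1A (−0.58) and NES (−1.09) down (adjusted p = 0.0319 and 0.0349, and adjusted p = 0.576 and 0.338 with an estimated correlation). Telomerase and shelterin genes had a median of 0.12 (adjusted p = 0.0319, and adjusted p = 0.338 with an estimated correlation). That list holds TERT itself, whose rise was set by the vector, and it was not tested without TERT. IRF7 (1.10), KRT8 (1.11), S100A4 (1.18) and RBL2 (0.67) also rose. CDKN2A had 0.49 (adjusted p = 0.0989), CDKN1A 0.69 (adjusted p = 0.392) and RB1 −0.06 (adjusted p = 0.715). Limma called 333 genes up and 135 down. The count was 15 without either TERT6 array, which leaves fewer arrays for the estimate of the spread, 48 and 31 without SV12 replicate 1 or 2, and 206 and 136 without ST11 replicate 1 or 2. A further probe of SERPINF1 and of S100A4 had the opposite sign, and with the mean of all probes these genes had 1.33 and 0.58 and, like CALD1 at −0.45, missed the threshold.

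The interaction asked whether the difference between cells with and without TERT itself differed with SV40EA, as ST11 minus SV12 against TERT6 minus parent. Cell cycle genes took part in numbers: 25 of 27 mitosis genes had a positive interaction that passed the test, with a median of 1.74, as had 21 of 30 replication genes (1.08) and 5 of 14 repair genes (0.56). TYMS, for thymidylate synthesis, differed by −2.05 in TERT6 minus parent and by 1.10 in ST11 minus SV12, PCNA, the sliding clamp of replication, by −1.57 and 1.02, and AURKB by −1.87 and 0.50. Smooth muscle genes went the other way, with TAGLN at 1.02 and −1.75 and ACTG2 at 1.56 and −2.49, and 6 of 12 contractile genes had a negative interaction that passed the test. So had 5 of 29 matrix genes, FBLN5 among them with 2.40 and −1.30. The adjusted p was 5.06e-18 for mitosis, 2.96e-12 for replication, 0.000241 for repair, 0.00015 for contractile and 0.000946 for matrix genes. These became adjusted p = 0.163, 0.0735, 0.163, 0.247 and 0.163 with an estimated correlation.

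The other called lists of the interaction were the secreted factors (median −0.71, adjusted p = 0.000952), of which CXCL12 alone passed the test, with a positive interaction (1.64), telomerase and shelterin genes (0.40, adjusted p = 0.00234; 2 of 14 positive by the test), cancer-testis antigen genes (−0.25, adjusted p = 0.0254; 0 of 13 in limma, where 4189 of all genes had an unadjusted p under 0.05) and neural markers (−0.55, adjusted p = 0.0347; 1 of 8 negative by the test). These became adjusted p = 0.411, 0.172, 0.242 and 0.247 with an estimated correlation. The cancer-testis antigen median lay slightly above the parent in each CodeLink array of a clone, from 0.11 in ST11-65 to 0.23 in SV12-68. The interaction of this list thus rests in part on the level of the parent array. TERT had an interaction of 0.59 (adjusted p = 0.085), CDKN1A 0.27 (adjusted p = 0.82), CDKN2A −0.36 (adjusted p = 0.28) and RB1 −0.28 (adjusted p = 0.226). Limma called 896 positive and 326 negative interactions among 13080 genes. The count was 267 and 265 without TERT6 replicate 1 or 2, and 360 and 420 without SV12 replicate 1 or 2, and TERT6 minus parent rests on 1 parent array.

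TERT6-65 was measured beside TIG-1-45 on all 3 platforms, which asks which differences the platforms share. Genes of cell division were lower in TERT6-65. Of 27 mitosis genes 24 fell (26 adjusted over the list alone), with a median of −1.95, including the cyclin genes CCNB2 (−2.43, or −1.44 and not called with the mean of all probes) and CCNB1 (−2.39), KIF20A (−2.37) and HMMR (−2.33). Of 29 replication genes 16 fell (24 adjusted over the list alone; median −1.28), including TK1 (−2.19), TYMS (−2.11) and MCM5 (−2.11), and of 14 repair genes 4 fell (8 adjusted over the list alone; median −0.83), including CHEK1 (−1.57) and H2AX (−1.50). Matrix and smooth muscle genes were higher: 8 of 29 matrix genes rose (12 adjusted over the list alone; median 0.56), including FBLN5 (1.68), LUM (1.27), COL4A1 (1.18) and POSTN (1.17). Of 11 contractile genes 3 rose (8 adjusted over the list alone; median 0.95), ACTG2 (1.72), TAGLN (1.15) and CALD1 (0.95). Of 23 secreted factors 7 rose and 1, CCL2 (−2.42), fell (12 and 3 adjusted over the list alone; median 0.42), with PLAT (2.77), EREG (1.97) and CXCL8 (1.69) highest.

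The adjusted p of these lists was 5.5e-18 for mitosis, 5.44e-12 for replication, 0.00278 for repair, 2.29e-08 for matrix, 1.08e-05 for contractile genes and 4.8e-05 for secreted factors. Each of these 6 lists had adjusted p = 0.429 with an estimated correlation. TERT rose by 7.09 (adjusted p = 0.0176), HBD by 5.96 (adjusted p = 0.00818), the chemokine scavenger gene ACKR4 by 5.17 (at least 56.2-fold on Agilent), WFDC1 by 4.57 and SRGN by 3.87. The growth and differentiation factor gene GDF15 rose by 2.23, TEK by 1.73, NES by 1.13 and TAP1 by 1.02. CYP1B1, an enzyme that oxidizes steroids and aromatic compounds, fell (−6.44, at least 118-fold on Agilent), as did S100A4 (−3.91), KCNK1 (−3.79, at least 8.2-fold on Agilent and 3.62-fold on CodeLink), NDN (−3.44, at least 11.2-fold on Agilent) and RARRES2 (−3.23). Of the regulators, the nuclear lamina gene LMNB1 (−2.04), ID1 (−1.28) and CDKN1C (−1.24) fell. Also lower were the imprinted genes MEST (−2.14) and PEG10 (−1.36), FOXF2 (−1.85), IFIT1 (−2.02) and TP53I3 (−1.01). CDKN2A rose by 1.12 (adjusted p = 0.044), CDKN1A had 0.38 (adjusted p = 0.123) and RB1 −0.06 (adjusted p = 0.786).

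Limma called 298 genes up and 544 down of 9129, and the correlation of the differences across genes was 0.574 for CodeLink with Agilent, 0.603 for CodeLink with Affymetrix and 0.755 for Agilent with Affymetrix. The count was 0 without the filter on dim probes, 0 without the Affymetrix arrays, 112 without the Agilent arrays and 1407 with Agilent values corrected by normexp, and the p-values measure platforms on the same pair of titles, not cultures. In the limma fits with a count of 0, 2686 genes without the filter and 1232 without the Affymetrix arrays had an unadjusted p under 0.05.

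TERT6-217 was set against TERT6-65 on Agilent and Affymetrix, 2 title numbers of 1 clone labelled immortal and, on Affymetrix, immortal-competent. CDKN2A fell (−5.34, adjusted p = 0.0369), as did its neighbour CDKN2B, which encodes the inhibitor p15 (−5.86, adjusted p = 0.036, at least 21.9-fold on Agilent). Cancer-testis antigen genes, silent in most adult tissues, were far higher: 4 of 6 rose (6 adjusted over the list alone; median 5.79, and 5.13 on Agilent with undetected levels at the floor of the array), MAGEA6 by 7.16 (at least 53.2-fold on Agilent), MAGEA12 by 6.58, MAGEB2 by 6.43 (at least 58.3-fold on Agilent) and SSX1 by 3.24. Of 30 mitosis genes 25 rose (30 adjusted over the list alone; median 2.10), including HMMR (3.03) and NUF2 (2.77), and of 34 replication genes 24 rose (30 adjusted over the list alone; median 1.33), including FEN1 (2.48). Of 15 repair genes 7 rose (9 adjusted over the list alone; median 0.98). TERT6-65 enters this and the preceding comparison with opposite signs, so opposite directions are built in to that extent. The 6 cancer-testis antigen genes are those of a list of 22 that passed the filters of both platforms. On Agilent 1 of the 6 was detected on both arrays. Genes silent elsewhere could pass by being high in TERT6-217, so their shared direction and list p are partly built in. Of 31 matrix genes 15 fell and 1 rose (24 and 1 adjusted over the list alone; median −1.24), among them FBLN1 (−6.14), POSTN (−5.44; at least 7.43-fold on Agilent) and COL11A1 (−4.21), while MFAP5 rose by 4.57 (at least 9.18-fold on Agilent).

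Further lists also moved in TERT6-217. Of 24 secreted factors 11 fell (13 fell and 4 rose adjusted over the list alone; median −0.82), including HGF (−4.99), IGFBP5 (−4.51), CCL2 (−4.04, at least 9.35-fold on Agilent) and PLAT (−3.75). Of 14 cholesterol synthesis genes 7 rose (9 adjusted over the list alone; median 0.99), among them ACAT2 (1.74), INSIG1 (1.51), STARD4 (1.49) and DHCR7 (1.34). Of 10 fibroblast markers 3 fell (4 adjusted over the list alone; median −0.68), with DCN (−3.95) and PDGFRA (−3.70, or −2.12 with the mean of all probes). The adjusted p was 3.13e-14 for mitosis, 2.47e-12 for replication, 0.000683 for repair, 8.57e-09 for matrix, 0.000178 for cancer-testis antigen genes, 0.00273 for secreted factors, 0.000173 for cholesterol synthesis and 0.00177 for fibroblast markers. Each of these 8 lists had adjusted p = 0.575 with an estimated correlation.

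Among single genes, HSD11B1, which activates glucocorticoids, rose by 7.04, ADGRE1 by 6.89 (at least 45.4-fold on Agilent) and APBB1IP by 6.83 (at least 71.8-fold on Agilent). CDH11, the cadherin of mesenchymal cells, fell (−9.58), as did the globin pseudogene HBBP1 (−8.44), the cyclin D2 gene CCND2 (−7.89), TRPA1 (−7.80) and NSG1 (−7.42). On Agilent these 5 were at least 264-fold, 485-fold, 146-fold, 280-fold and 58-fold lower. The HBB gene of beta-globin (−4.08, at least 9.65-fold on Agilent), the imprinted MEG3 (−3.06), TBX2 (−2.86), FOXF1 (−1.71) and NES (−3.63) fell, while PEG10 (1.97), KRT18 (2.58), LMNB1 (1.87) and CNN1 (1.47) rose. Of 19 interferon-stimulated genes 4 rose, among them IFIT1 (2.29), IFI27 (1.96) and OAS3 (1.73, at least 3.26-fold on Agilent), and MX1 fell (−2.21, at least 3.52-fold on Agilent), with adjusted p = 0.257 for the list. TERT fell (−4.62, adjusted p = 0.0345), RB1 rose by 0.79 (adjusted p = 0.0487) and CDKN1A had −0.36 (adjusted p = 0.174). Limma called 823 genes up and 792 down of 11001, and across genes the platforms' differences correlated at 0.815. The count was 697 with the mean of all probes of a gene and 0 without the filter, where 4293 genes had an unadjusted p under 0.05 in limma. As before, these p-values measure platforms, not cultures.

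On Affymetrix alone, TERT6 at 3 title numbers was compared with the 3 arrays of mortal cells. No gene passed the limma test, and 994 of 12189 had an unadjusted p under 0.05, with a smallest adjusted p of 0.186. The highest differences were in GPR65, an acid-sensing receptor (4.46; 9.87 ± 0.68, SD, n = 3, against 5.41 ± 0.97, n = 3), LIMCH1 (4.04), ACKR4 (3.96), DNAJC6 (3.86) and IFI27 (3.74, or 2.42 with a pseudocount of 64). The lowest were in EPB41L3 (−5.45), the chemokine gene CXCL12 (−5.40), GABRB1 (−4.15), the hyaluronan synthase gene HAS2 (−4.10) and OCIAD2 (−4.01). With a pseudocount of 1 another probe set stood for CXCL12, at −2.45, so its 2 values differ by probe set. CDKN2A differed by −2.0 (adjusted p = 0.717) with an SD of 3.00 among the TERT6 arrays, TERT by 0.07 (adjusted p = 0.996), CDKN1A by 0.37 (adjusted p = 0.773) and RB1 by 0.08 (adjusted p = 0.954). All 35 replication genes and all 31 mitosis genes were lower, with medians of −1.20 (adjusted p = 8.62e-17) and −1.44 (adjusted p = 1.53e-15). Both lists had adjusted p = 0.48 with an estimated correlation. By array, the mitosis median was −2.09 at TERT6-65, −2.05 at TERT6-121 and −0.13 at TERT6-217, and −0.10 and −0.11 in TERT5 and TERT8. Without TERT6 replicate 1 limma called 8 genes, and without TERT6 replicate 3 it called 125.

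The other called lists were repair (−0.64, adjusted p = 0.000827), interferon-stimulated genes (0.39, adjusted p = 0.000385), cancer-testis antigen genes (2.0, adjusted p = 0.000827), contractile genes (0.26, adjusted p = 0.00347), cholesterol synthesis (0.38, adjusted p = 0.0042), glycolysis and hypoxia genes (−0.29, adjusted p = 0.00468), matrix genes (0.16, adjusted p = 0.0457) and senescence regulators (−0.39, adjusted p = 0.0482). With an estimated correlation the lowest of these was adjusted p = 0.48. The cancer-testis antigen median by array was −0.16 in TERT5, 0.14 in TERT8, 0.34 at TERT6-65, 2.08 at TERT6-121 and 5.72 at TERT6-217. It covers the 6 of 22 members that passed the filter on mean level, which high values at TERT6-217 helped them to pass. The matrix median was 0.61 at TERT6-65 and at TERT6-121 but −0.48 at TERT6-217, where 23 of 31 genes were lower, and without TERT6-65 or TERT6-121 the list's median was 0.0085 and 0.047 and its call was lost, as it was without the parent or TERT8. With each array left out in turn 4 of the 10 called lists of this comparison kept their calls.

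TERT6 against the mortal TERT clones TERT5 and TERT8 set cells against each other that all carry TERT. TERT differed by −2.26 (adjusted p = 0.766), CDKN2A by −1.97 (adjusted p = 0.816), CDKN1A by 0.41 (adjusted p = 0.834) and RB1 by 0.05 (adjusted p = 0.982). The highest differences were in DNAJC6 (4.08), GPR65 (3.91), IFI27 (3.84, or 2.45 with a pseudocount of 64), EMB (3.58) and GATA3 (3.46, or 2.27 without TERT5). The lowest were in CXCL12 (−4.54), HAS2 (−4.10), GABRB1 (−3.81), OCIAD2 (−3.69) and TMEM200C (−3.43). CXCL12 had −1.73 by the other probe set that stood for it with a pseudocount of 1. No gene passed the limma test, and 825 had an unadjusted p under 0.05. Replication (−1.15, adjusted p = 2.4e-14) and mitosis genes (−1.38, adjusted p = 8.85e-13) were lower, each with adjusted p = 0.555 with an estimated correlation. Lower too were repair genes (−0.79, adjusted p = 0.00295), glycolysis and hypoxia genes (−0.29, adjusted p = 0.00132) and senescence regulators (−0.60, adjusted p = 0.0232). Interferon-stimulated (0.44, adjusted p = 0.00016), cancer-testis antigen (1.71, adjusted p = 0.0066) and cholesterol synthesis genes (0.45, adjusted p = 0.00295) were higher. With an estimated correlation none of these was under adjusted p = 0.555. The cancer-testis antigen genes were again the 6 of 22 that passed the filter on mean level.

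Mortal TERT clones against the parent asked what differed with TERT while the lifespan stayed limited (n = 2 against n = 1). TERT differed by 6.99 (adjusted p = 1.0), CDKN2A by −0.07, CDKN1A by −0.10 and RB1 by 0.06. The metalloproteinase gene MMP10 (2.97), IL32 (2.79), the Notch ligand gene DLL4 (2.73), PLIN5 (2.66, or 1.62 with a pseudocount of 64 and 1.28 with the mean of all probe sets) and DHRS13 (2.62, or 1.58 with a pseudocount of 64) were highest. The enkephalin gene PENK (−4.42), the retinoid carrier gene CRABP2 (−4.16), SERPINF1 (−4.00), ITGA7 (−3.55) and PRXL2A (−3.53) were lowest. The 1 further probe set of PENK had the opposite sign, and 2 of 5 further probe sets of PLIN5 had the same sign. No gene passed the limma test, and 449 had an unadjusted p under 0.05. Simulated 4-fold changes were not recovered in this comparison or the preceding one, so the counts of 0 say little. Of 14 contractile genes 13 were higher, with a median of 0.53 (adjusted p = 3.84e-08, and adjusted p = 0.219 with an estimated correlation). Secreted factors had a median of 0.45 (adjusted p = 0.000405, and adjusted p = 0.763 with an estimated correlation).

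On Agilent, ST11-196 stood out by its interferon-stimulated genes, which cells make in response to viral nucleic acid or interferon. All 26 lay above the parent, with a median difference of 4.14 at percentile 100 of random lists, led by BST2 (8.44), IFI27 (8.39), MX2 (7.68) and MX1 (7.04). Against the mean of the TERT6 arrays the median was 4.43, with XAF1 (5.36), IFI27 (5.29), IFI6 (5.05), IFIT1 (4.83) and the kinase gene PRKCZ (4.60) highest. The highest and lowest single genes of this paragraph are ranked among those well above background on all arrays compared. In ST11 on CodeLink, at lower title numbers, the same list had medians of 0.08 and −0.05. All 34 replication genes lay above the parent in ST11-196 (median 1.55), and 25 of 30 mitosis genes did (0.53), while 29 of 31 matrix genes (−2.36, and −2.23 with undetected levels at the floor) and 10 of 10 fibroblast markers (−2.42) lay below. The lowest genes against the parent were CDH11 (−7.72), TBX2 (−7.49), TMEM98 (−6.90), PLEKHF1 (−6.46) and SPON2 (−6.45), and against TERT6 HBG1 (−7.80), SPON2 (−7.67), SDC2 (−6.89), SLC14A1 (−6.54) and HBE1 (−6.45). TERT exceeded the parent by 10.82, CDKN2A by 3.83 and RB1 by 1.05. CDKN1A differed by 0.12. The ST11-196 array was alone on its slide, so the slide and the clone cannot be told apart, and no test was made on Agilent alone.

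TERT6-65 on Agilent had globin genes among its highest, with HBG1 at 9.21, HBBP1 at 8.88, HBE1 at 6.79 and HBD at 6.71 above the parent beside TERT at 9.34. Single genes of this paragraph, too, are ranked among those well above background on both arrays. Its lowest genes were CXCL12 (−6.15), GAL (−5.36), CRABP2 (−4.77), CYB5R2 (−4.72) and BACE2 (−4.31), and CDKN1A and RB1 differed by 0.47 and −0.15. All 34 replication genes (median −1.72, and −1.51 with undetected levels at the floor) and all 30 mitosis genes (−2.23) lay below the parent. TERT6-217 lay highest above the parent in CSAG1 (7.20), PLAC8 (6.92), CSAG4 (6.65), MAGEB2 (6.44) and HCLS1 (6.13). Of 12 cancer-testis antigen genes 11 were higher, but 2 of the 12 were well above background on both arrays. A probe above background on 1 array passed the filter, and 3 of the 12 genes were detected in TERT6-65 or the parent. These 12, of a list of 22, were thus kept largely because they were high in TERT6-217. With undetected levels at the floor of the array the list's median was 5.64, whereas the mitosis median was −0.03. The lowest were KRT19 (−7.19), MAGED4B (−6.86), OCIAD2 (−6.80), ADIRF (−6.68) and ANKRD35 (−6.39). TERT lay 4.77 above the parent, RB1 0.62 above it, and CDKN1A differed by −0.05.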

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

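Of the tests here, those of an aberrant parent array, a mislabelled sample, the normalization of the platforms and cells of another type were chosen after the result was seen, and the test of MTAP, the cell cycle test and the splits of the arrays before it. For 1222 genes the difference between cells with and without TERT itself differed with SV40EA on CodeLink, by the interaction test. CYP1B1 had an interaction of 6.75 on the log2 scale, SERPINF1 5.5, S100A4 4.93, MEST 4.27 and TMSB15A 3.48. WFDC1 had −3.75, ACTG2 −4.05, SPON2 −4.24, FMO4 −4.26 and HBD −5.36. CYP1B1 stood at −4.72 in TERT6 minus parent and at 2.03 in ST11 minus SV12, SERPINF1 at −2.58 and 2.92, S100A4 at −3.75 and 1.18, MEST at −2.89 and 1.38 and TMSB15A at −2.80 and 0.68. WFDC1 stood at 3.73 and −0.02, with no array above background in SV12 or ST11, so that its second difference and its interaction are no exact sizes, ACTG2 at 1.56 and −2.49, SPON2 at 4.02 and −0.22, FMO4 at 2.13 and −2.13 and HBD at 5.53 and 0.17. With the mean of all probes the interaction was 2.54 for SERPINF1 and 2.65 for S100A4. The count was 267 and 265 without TERT6 replicate 1 or 2, and 360 and 420 without SV12 replicate 1 or 2.

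The interaction rests on 1 CodeLink array of the parent, so an aberrant parent array was set against it. The 1175 called genes that were measured on all platforms had a median TERT6-65 minus parent difference, signed against the interaction, of 0.45 on Agilent and 0.48 on Affymetrix, each with its own parent array and against 0.62 on CodeLink, which argues against an array fault as the whole cause. A restriction to cell cycle genes was also tested: with the mean of the mitosis list as a covariate 0% of the 1171 called genes outside the replication, mitosis and repair lists stayed called in limma, but their median absolute change went from 1.04 to 1.27 while its standard error went from 0.177 to 1.11, so the calls ended for want of precision. Limma called 51 members of these lists and 9.0% of the genes outside them, so the calls were not of list members alone. Cell cycle genes outside the lists were not told apart, so this share cannot decide on a wider cell cycle pattern. Whether growth state drives the rest stays open. The clone and the vector cannot be told apart in any of these values.

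The cell cycle genes of TERT6-65 lay below the parent on every platform. Over the 27 mitosis genes measured on all 3, the median was −1.57 on CodeLink, the value nearest 0, −2.21 on Agilent and −2.09 on Affymetrix, which argues against a fault of the normalization of a single platform. Cells without fibroblast markers, if they made up most of the culture, would lower these markers by about as much, but their median was 0.077 on CodeLink, the lowest, 0.57 on Agilent and 0.34 on Affymetrix, above the mitosis median by more than the spread of the 10 markers (0.459, 0.64 and 0.289), with S100A4 alone below it, which argues against such cells as the whole cause. A smaller share of other cells, or cells that share the fibroblast markers, stays open: without the filter the highest of the 4 lists of other markers had a median of 0.88, for endothelial markers on Agilent, where 2 of 9 were well above background, and of the neural markers 25%, MAP2 and NES, were well above background and over 2-fold higher in TERT6-65. A slower growth of TERT6-65 may also account for the values and was not tested.

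CDKN2A in TERT6-217 minus TERT6-65 was −4.70 on Agilent and −5.98 on Affymetrix on the log2 scale. MTAP, next to CDKN2A in the assembly GRCh38.p14, changed by −4.11 on Affymetrix and was at least 6.22-fold lower by its brightest Agilent probe, and CDKN2B changed by −5.24 and was at least 21.9-fold lower, as loss of these genes would give, while KLHL9 on 1 side changed by −0.30 on Agilent and −0.41 on Affymetrix. On the other side TUSC1 changed by −2.49 and −2.17, PLAA by 0.02 and −0.03 and TEK, beyond it, by −1.73 and −1.41, so the lower genes were no unbroken row. Against a loss of whole genes from all cells, 1 of 2 CDKN2A probes and 1 of 3 MTAP probes were well above background in TERT6-217 on Agilent, this MTAP probe at least 6.3-fold higher than in TERT6-65, where it was undetected, and HACD4, beyond KLHL9, was also lower (−4.74 on Affymetrix, at least 11.1-fold on Agilent). At TERT6-121 CDKN2A changed by −2.67 from TERT6-65 and TUSC1 by −3.24, with MTAP at 0.38 and CDKN2B at −0.01. Silencing may thus account for part of the fall, and the cause stays open without an analysis of DNA. A mislabelled sample of cells with as little TERT as the parent is argued against by TERT, 2.22 above the parent on Affymetrix and 4.77 on Agilent. The arrays measure transcripts and not the vector, so a mislabelled sample of other cells that express TERT stays open.

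For SV40EA, of 34 splits of the 7 arrays the real one called 2030 genes and the highest other called 2, so 1 split reached the real count. This would argue against chance only if single arrays could be exchanged. The other splits also leave the SV40EA difference in the spread between arrays, which lowers their counts. For clones chance cannot be excluded, since 6 of the 7 arrays come in pairs of a clone and 3 splits keep these pairs whole. For TERT, chance cannot be excluded: the real split called 6 genes and the highest other, TERT6 and SV12 against the parent and ST11, called 100, so 2 splits reached the real count. That split follows the interaction of both vectors, a structure of the samples. For TERT6 against mortal cells the 10 splits are too few for a share under 0.05; limma called 0 genes in the real split, with 994 at an unadjusted p under 0.05, and 0 in the highest other, so all 10 gave as many.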

How the results depend on the processing

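All alternatives were planned ahead. Counts of called genes stayed within 1.5 times for SV40EA (1905 to 2047), TERT (6 to 8), ST11 against SV12 (433 to 550) and the interaction (1153 to 1299) under the authors' values, median scaling, no background correction, other filters, the mean of all probes and an intensity trend. With the title number as a covariate the SV40EA count was 768 and the TERT count 1, and with a 4-group model 3394 and 270. Leaving out each array in turn gave 690 to 4007 genes for SV40EA, 2 to 468 for TERT, 15 to 468 for ST11 against SV12, 265 to 864 for the interaction and 0 to 125 for TERT6 against mortal cells. For both 3-group Affymetrix comparisons it gave 0. TERT6-65 against the parent called 1407 genes with Agilent normexp values, 0 without the filter, 112 without the Agilent arrays and 0 without the Affymetrix arrays. TERT6-217 against TERT6-65 called 0 without the filter and 697 with the mean of all probes. Without the parent array the SV40EA effect is ST11 minus TERT6 by construction. The TERT effect is then ST11 minus SV12, and its list medians reversed to 0.42 for replication, 0.17 for mitosis, 0.36 for repair and −0.16 for matrix genes. Leaving out each array gave −0.17 to 0.42, −0.77 to 0.17, −0.094 to 0.36 and −0.16 to 0.043 for these lists. RB1 reversed to an interaction of 0.57 with the mean of all probes. Among probes well above background on all 4 Agilent arrays the cancer-testis medians reversed to −0.20 in TERT6-65 and −0.18 in TERT6-217, and the endothelial median of ST11-196 minus TERT6 to −3.02. That filter removes genes undetected in the parent by construction, so it says nothing about those. Other than in these constructions the cause was not tested. Of the named genes' changes under alternatives 3049 kept direction and side of the threshold, 641 lost the call, 10 gained it and 1 reversed. Of the list medians 2108 kept both, 115 lost the call, 47 gained it and 4 reversed. With an estimated correlation no list call held. That form of camera rests on 1 to 4 residual degrees of freedom, so it could hardly pass and cannot show that correlation made the calls. Nor can it show that correlation played no part. For mitosis genes the estimate was 0.779 for SV40EA and 0.936 in TERT6 against mortal cells, far above the preset 0.01. The p-values at the preset may therefore be too small for such lists. For mitosis genes in TERT6-217 against TERT6-65 the estimate was −0.016, below the preset, from a fit with 1 residual degree of freedom. Even so, camera's unadjusted p went from 1.84e-15 to 0.0701. The authors' values shifted the median of all genes to −0.11 for TERT6-65 against the parent and to 0.12 for TERT6-217 against TERT6-65. No paired analysis was possible because the replicate numbers name arrays and pair none. The block for slide or scan date was not run, since each CodeLink array had its own slide and all 7 shared 1 date. Signal over background limits dim genes, and Affymetrix values had no detection calls.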

Other observations

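The globin genes were singled out after their values were seen, and no test was made of them beyond the comparisons above. HBD, which encodes the delta chain of hemoglobin and is normally expressed in red cell precursors, lay above the parent by 5.27 and 5.79 on the log2 scale in TERT6 on CodeLink, but at −1.25 and −1.24 in SV12 and at −1.08 and −1.07 in ST11. On Affymetrix HBD lay above the parent by 1.27 in TERT5, 3.89 in TERT8, 5.90 in TERT6-65 and 7.07 in TERT6-121, and at −0.84 in TERT6-217. HBE1, the embryonic epsilon chain gene, lay above it by 3.67, 4.22, 5.55, 1.46 and 1.25 in the same order. The pseudogene HBBP1 had 2.83, 7.95, 8.39, 4.06 and 1.11, and HBB −0.17, 1.27, 3.02, 3.96 and −0.65. On Agilent HBG1, the gamma chain gene, lay 9.21 above the parent in TERT6-65 and 0.78 in TERT6-217, and at −2.80 in ST11-196.

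Across the alternatives that measured them, 25 of the 60 named genes called for SV40EA kept their call in each, among them IL1B, CXCL8, CDKN2A, FEN1, BLM, FOXF1 and SPON2. For TERT 1 of 6 did, TERT itself, and for ST11 against SV12 6 of 28 did: CXCL6, EPB41L3, RTEL1, TERT, THBS1 and TP53I11. For the interaction 28 of 45 did, for TERT6-65 against the parent 0 of 52 and for TERT6-217 against TERT6-65 0 of 69. In both of the latter comparisons the alternative without the filter called 0 genes. No named gene could therefore keep its call in each alternative there. Of the called lists, with each array left out in turn, 6 of 7 kept their call for SV40EA, 1 of 2 for TERT, 3 of 9 for ST11 against SV12, 8 of 9 for the interaction and 4 of 8 for TERT6 against the mortal TERT clones. A reversed sign was not counted as a lost call here. Without the parent array the mitosis list for TERT reversed to a median of 0.17.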
